A study of Pythium myriotylum with 18 samples.

How the data were processed

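The series measured messenger RNA of Pythium myriotylum strain SWQ7, a plant-pathogenic oomycete, by RNA sequencing of mycelium. The mycelium shared a sealed bipartite plate, whose divider leaves only the air in common, with Pythium oligandrum strain GAQ1, a mycoparasitic oomycete, or grew in such a plate without it. Mycelium was collected 48, 60 and 72 h after inoculation. Per the labels, each of the 6 combinations of exposure and time had 3 biological replicates, which gave 18 libraries prepared with a stranded mRNA kit. Groups and replicate numbers were taken from the sample titles.

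The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and HTSeq, with no versions. Their settings, the genome build and the annotation are not given in the sources used here, nor is whether counting used the strand. The authors deposited a table of raw read counts per gene and a table of FPKM values (counts divided by library total and gene length) for the same 18 libraries. The count table held 17768 genes and the table of FPKM values 19878, of which the additional 2110 were at 0 in every library. Each deposited FPKM value could be rebuilt from the count, the library total and a fixed length per gene, so FPKM was not an independent measurement. The lengths obtained this way were whole numbers within 0.001 for all 13178 genes with a maximum of at least 100 counts, and 99.83% of lengths were multiples of 3, so they are coding lengths. Genes carry numbers only, and the files do not pair them with names, products or positions. None of the 39 gene lists fixed by product words before the data were examined could therefore be tested, and no genome or annotation was used here. Reads shared between near-identical or overlapping genes could not be assessed, and every count of a single gene carries that limit.

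Library totals ran from 31937586 to 38286628 counts. A count of 3 in a library was taken as the floor per library where a group was at 0. As a group mean this floor corresponds to 0.0800 to 0.0941 CPM, the count scaled by the TMM-scaled library total (TMM scaling is given below). Floors and counting intervals cover counting error only. The intervals pool the counts of a group's replicates, so they leave out the spread between replicates. The reads carry no molecular identifiers.

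Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups, which retained 15101 and left out 2667. Libraries were scaled by TMM, and a group-means model of all 18 libraries without a replicate block was fitted with glmQLFit (robust) and tested with glmQLFTest. The common biological coefficient of variation was 0.375. Contrasts were exposed minus non-exposed at each time, the change of that effect over the 3 times (joint test), the change from 48 h to 72 h, and 72 h minus 48 h within exposed and within non-exposed mycelium. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Rose and fell mean called higher and called lower in exposed mycelium. Log2 fold changes are edgeR's with a prior count of 0.125, and each SE is the fold change divided by the square root of the F statistic, an approximation. CPM values use the TMM-scaled totals. Overlaps of calls between times were set against the number for independent lists. No library is shared between the times, but the 3 comparisons use the same fitted spread per gene. Genes with little spread are thus called more easily at every time, which the number for independent lists does not allow for.

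With no names, the rule fixed before the data were examined printed the 2 identifiers with the largest rise and the 2 with the largest fall. It was applied over the 3 exposure comparisons together, among genes with adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the 3 exposed and the 3 non-exposed libraries. The pooling over comparisons was chosen after the data were seen.

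Library-level measures were compared with exact two-sided permutation tests that relabelled exposure within each time (8000 relabellings for all 18 libraries, with 5 measures in the family). With 3 libraries against 3 at a single time, the smallest possible p is 0.1. Correlations of log2 CPM (prior count 2) across genes describe libraries, and genes are not independent replicates. Replicates of a group differed by far more than sampling noise (chi-square per gene 32.0 to 530.7), so none was treated as a duplicate.

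The edgeR and DESeq2 tests, limma voom with sample quality weights and limma on a log2 scale were run on simulated counts. These had the means and library sizes of the data, a spread per gene fitted to the data, and 200 genes changed per comparison. Of genes changed 4-fold, edgeR recovered 64% at 48 h, 63% at 60 h and 57% at 72 h. Of genes changed 2-fold, it recovered 18%, 23% and 15%. Wrong calls made up 2.38%, 3.37% and 4% of its calls, against 25%, 24.5% and 21.8% for DESeq2 1.42.0 on the same simulated counts. The simulation changed 200 of 15101 genes per comparison, whereas 2921 to 6450 were called in the data. Real groups also differed in the spread between their replicates (chi-square per gene 32.0 to 530.7). These rates therefore describe the simulated counts and were not shown to hold for the real calls.

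Alternatives fixed before the data were examined were DESeq2 size factors, library totals without TMM, no expression filter, the DESeq2 test, the replicate number as a block, only the compared groups in the fit, each replicate left out in turn, and limma 3.58.1 on log2(FPKM + 1), on log2(FPKM + 0.1) and without a filter. Further alternatives were chosen after seeing the data: limma voom with sample quality weights, removal of each library's trend with coding length, thinning of every library to the smallest total, and fits without libraries that stood apart. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.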

Results

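Mycelium of Pythium myriotylum was sequenced with and without exposure to volatiles of Pythium oligandrum at 48, 60 and 72 h, with 3 libraries in each of the 6 groups. Library totals ran from 31937586 to 38286628 counts. They averaged 33045732 in non-exposed and 36992965 in exposed mycelium at 48 h, 33713193 and 35662138 at 60 h, and 35807915 and 34715540 at 72 h. At 48 h and 60 h every exposed library was larger than every non-exposed one. Of the 15101 genes tested, 8882 (58.8%) changed with exposure at 1 or more of the 3 times.

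Exposed and non-exposed libraries lay on opposite sides of the first principal component of log2 CPM, which held 39.8% of the variance. The second held 20.1% and separated libraries within 2 groups. In the exposed 48 h group, replicates 2 and 3 correlated at r = 0.979 across genes, and replicate 1 correlated at 0.910 with them on average but at 0.960 with the exposed 60 h libraries. In the non-exposed 60 h group, replicates 1 and 2 correlated at 0.956, and the lowest correlation, involving replicate 3, was 0.879. The other 4 groups had mean correlations between 0.970 and 0.981 within the group.

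**Figure D1:**
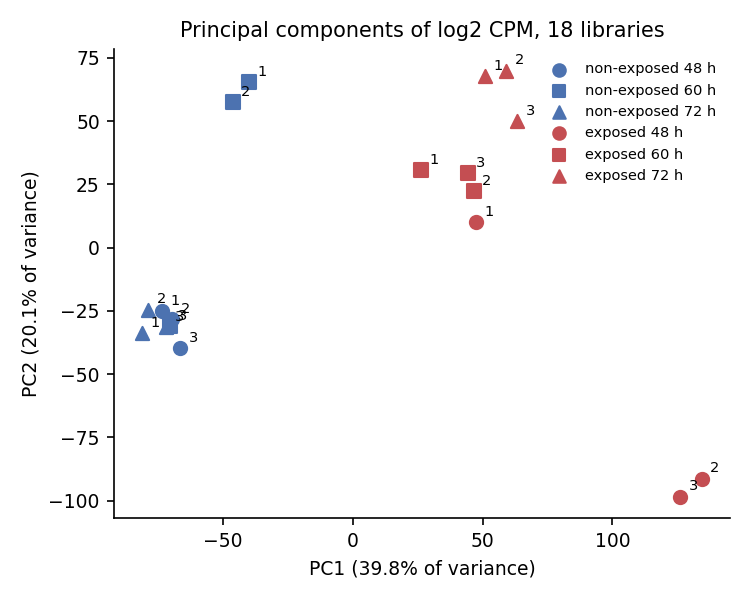
Principal components 1 and 2 of log2 CPM for the 18 libraries, with the percent of variance on each axis; colour gives exposure, marker shape gives time and the digit beside each point is the replicate number. Replicates 2 and 3 of exposed 48 h lie apart from replicate 1, and replicates 1 and 2 of non-exposed 60 h lie apart from replicate 3.

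The first comparison asked which genes differed between exposed and non-exposed mycelium after 48 h. The 48 h response took in 6450 genes (42.7% of those tested), of which 3569 rose and 2881 fell. A change of at least 2-fold was fitted for 2278 of the risen and 1811 of the fallen genes. The risen genes together held 22.9% ± 0.81 of all counts in non-exposed mycelium and 46% ± 8.0 in exposed mycelium (SD, n = 3 each). The fallen genes went from 19.4% ± 1.5 to 6.87% ± 1.4. These are shares of genes picked for their change, so they describe its size and do not test it. The next 900 genes by mean abundance after the first 100 mostly rose where they changed (363 rose and 108 fell, or 247 and 192 with library totals as the only scaling), while the 5101 least abundant genes mostly fell (617 rose and 919 fell, or 433 and 1222). The groups did not overlap for 53.7% of tested genes, where chance gives 10%. Without TMM, with library totals as the only scaling, 2192 genes rose and 4250 fell, and the median log2 fold change of all genes moved from 0.05 to -0.30. A fit of only the 6 libraries compared called 5212 genes. With only replicate 1 of the exposed 48 h group, a setting chosen after seeing the data, 2856 genes were called, 2446 of them among the 6450. With only replicate 2 or only replicate 3, 5359 and 5836 genes were called.

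The gene g14859 (coding length 1515 bp) was not detected in the 3 non-exposed 48 h libraries and reached 29.2 ± 28.6 CPM in the exposed ones (SD, n = 3), with 248 to 1878 counts. That is at least 353.6-fold higher, against a floor of 3 counts per library, with an adjusted p of 5.23e-05. Without exposed replicate 3, which held the 1878 counts, the bound was at least 157.4-fold higher. At 60 h g14859 stood at 5.50 ± 2.93 CPM with exposure and 2.46 ± 1.20 without (adjusted p = 0.308). At 72 h it rose again, with 3.68 ± 2.42 CPM against 4 counts in the 3 non-exposed libraries together (adjusted p = 0.00151). The gene g16808 (coding length 279 bp) reached 102.4 ± 94.1 CPM in exposed 48 h mycelium against 1 count in the 3 non-exposed libraries, an adjusted p of 0.000296. The ratio of the pooled counts was 10600 with a 95% counting interval of 1910 to 419000, which leaves out the spread between replicates. Its 9313 exposed counts lay almost entirely in replicates 2 and 3, with 3631 and 5668 counts against 14 in replicate 1. g16808 was not called at 60 h (adjusted p = 0.261) or 72 h (adjusted p = 0.444), where exposed libraries held 2 to 9 counts and 3 to 4 counts. A difference of its effect between times was not shown (joint test, adjusted p = 0.607).

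At 60 h the comparison called 2921 genes (19.3%), of which 1360 rose and 1561 fell, 785 and 967 of them by at least 2-fold. The 100 most abundant genes, with means of 1460 CPM or more, moved largely one way: 70 rose and 1 fell, with a median log2 fold change of 0.74. With library totals as the only scaling 61 of these 100 rose and 1 fell. Among the 5101 least abundant genes, 283 rose and 436 fell (226 and 550 with library totals). The genes that fell at 60 h held 13.5% ± 0.51 of counts in non-exposed 60 h mycelium, compared with 8.53% ± 0.88 and 8.66% ± 0.37 in non-exposed mycelium at 48 h and 72 h, and 5.27% ± 0.32 in exposed 60 h mycelium. With library totals as the only scaling, 1000 genes rose and 2256 fell. The count of calls was 1348 without replicate 2 of the exposed 60 h group, 1909 without replicate 3 of that group, 529 with only the 6 libraries compared in the fit, and 4441 with the non-exposed 48 h and 72 h libraries as the control. With those controls 2553 genes rose and 1888 fell, and 1648 of the 2921 calls were shared. The groups did not overlap for 31.4% of tested genes, where chance gives 10%.

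After 72 h, 3652 genes (24.2%) differed, with 1933 risen and 1719 fallen, of which 1260 and 1150 changed by at least 2-fold. Again the 100 most abundant genes rose for the most part, with 68 risen and 3 fallen (51 and 6 with library totals as the only scaling). The genes that rose went from 24.2% ± 3.1 of counts without exposure to 41.1% ± 1.2 with it, and those that fell went from 14.6% ± 0.84 to 5.16% ± 0.22. In the genes that fell, the median log2 fold change was -1.55 (-1.54 with genes at 0 in a whole group set to their bound), and in those that rose it was 1.32. Exposed and non-exposed libraries did not overlap for 56.0% of tested genes, against 10% by chance. At least 100 counts in each non-exposed library and at most 3 in each exposed one were found for 18 genes, compared with 7 genes at 48 h and 1 at 60 h. The reverse held for 4 genes at 72 h, 2 at 48 h and 2 at 60 h. Library totals as the only scaling gave 1327 risen and 2602 fallen genes. A fit of only the 6 libraries compared called 6578 genes, against 5212 at 48 h in the same setting. Whether 48 h or 72 h had more calls therefore depended on the fit. Without replicate 2 of the exposed 72 h group 2298 genes were called. Sample quality weights gave 7695, against 9413 at 48 h.

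The genes g11821 (coding length 1533 bp) and g11212 (coding length 1428 bp) had no counts in any exposed 72 h library. Without exposure, g11821 stood at 32.6 ± 13.0 CPM and g11212 at 18.7 ± 7.67 CPM (SD, n = 3 each). With the floor of 3 counts per library, g11821 was at least 347.6-fold lower (adjusted p = 0.00146) and g11212 at least 199-fold lower (adjusted p = 7.8e-05). Both were lower at the other times too. At 48 h g11821 had 0.08 ± 0.11 CPM against 7.21 ± 1.87 (adjusted p = 0.00511) and g11212 had 0.06 ± 0.10 CPM against 14.01 ± 0.533 (adjusted p = 7.36e-05). At 60 h the non-exposed libraries were uneven, with 2 to 441 counts of g11821 and 56 to 242 counts of g11212, and the adjusted p was 0.0116 and 0.00294. For g11821 the 441 counts lay in non-exposed replicate 3, against 2 and 33 in replicates 1 and 2. Exposed 60 h libraries held 0 to 2 counts of it, so the groups overlapped.

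**Figure D2:**
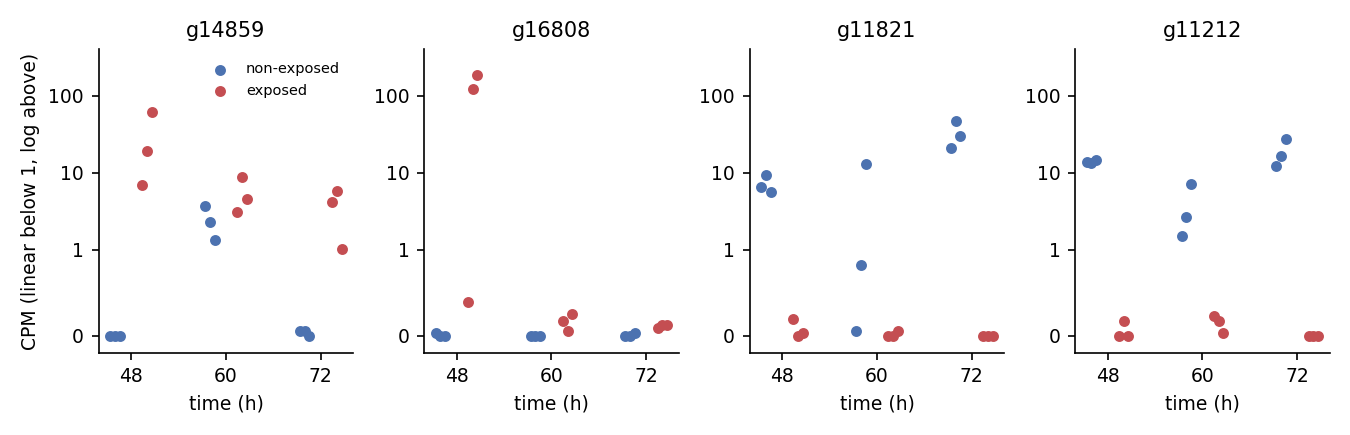
CPM of g14859, g16808, g11821 and g11212 in each of the 18 libraries by time (3 points per group, in replicate order; axis linear below 1 and logarithmic above). g11821 and g11212 lie at 0 in all 3 exposed 72 h libraries, and g16808 exceeds 100 CPM only in replicates 2 and 3 of exposed 48 h.

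**Figure D3:**
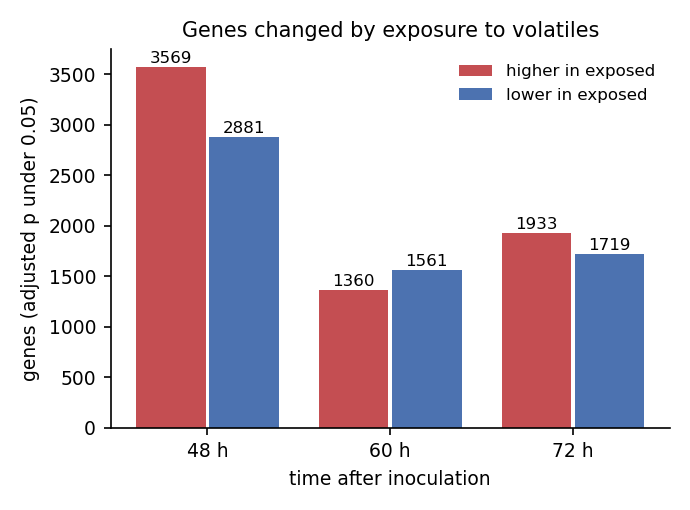
Number of genes called higher or lower in exposed than in non-exposed mycelium at each time (edgeR, adjusted p under 0.05, 15101 genes tested, TMM scaling). Bars run from 3569 risen genes at 48 h to 1360 at 60 h. With only the libraries compared in each fit, 72 h had more calls (6578) than 48 h (5212).

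The overlap of calls asked whether the 3 times shared responding genes. There were 441 genes that rose at all 3 times and 339 that fell at all 3, where 41.1 and 33.9 are the numbers for independent lists. Those numbers do not allow for the spread per gene that the 3 comparisons share in the fit. The 441 risen genes had median log2 fold changes of 1.97, 1.46 and 1.60 at 48, 60 and 72 h. The 339 fallen genes had medians of -2.55, -2.21 and -2.46 (-2.39, -2.12 and -2.35 with genes at 0 in a whole group set to their bound). The test of the change from 48 h to 72 h called 79 of the 441 and 29 of the 339. Pairs of times shared more genes in the same direction than independent lists would: 1000 rose and 882 fell at both 48 h and 72 h, for which independence gives 456.8 and 328.0. Across the 15101 genes, log2 fold changes correlated between 48 h and 72 h at r = 0.625 (Spearman's rho 0.455), between 48 h and 60 h at r = 0.492 (rho 0.413), and between 60 h and 72 h at r = 0.469 (rho 0.372). Opposite calls at 48 h and 72 h were made for 177 genes. With the 60 h controls replaced by the non-exposed 48 h and 72 h libraries, 2108 genes changed the same way at all 3 times. In that setting the times share control libraries, and how much this adds to the overlap was not estimated: unchanged groups simulated against them gave 0 calls at each time and so 0 shared genes.

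The change of the exposure effect with time was tested directly. In the joint test over the 3 times, 4188 genes (27.7%) changed their effect, and from 48 h to 72 h the effect increased for 1153 genes and decreased for 1679. Increase and decrease, here and below, refer to the signed log2 fold change, so a fall that faded by 72 h counts as an increase. Among the 1533 genes that fell at 48 h and were not called later, 544 had a called change from 48 h to 72 h. The same held for 963 of the 2012 genes that rose at 48 h and were not called later. Of the 3545 genes called at 48 h and at no other time, 1700 passed the joint test, as did 350 of the 839 called only at 60 h and 482 of the 1202 called only at 72 h. For the rest a difference between times was not shown. The 3569 genes picked as risen at 48 h had a median log2 fold change of 1.21 at 48 h and 0.31 at 72 h, where 68.3% were also above 0. In reverse, the 1933 genes picked as risen at 72 h had medians of 1.32 at 72 h and 0.83 at 48 h. At 48 h 83.0% of these were above 0. Picking genes at a time by itself favours larger values at that time. Of the 100 most abundant genes 22 rose and 5 fell at 48 h (8 and 21 with library totals as the only scaling), and for 27 of them the effect increased from 48 h to 72 h while for 8 it decreased. The split of 40.7% increases from 48 h to 72 h became 50.5% with library totals as the only scaling. With only replicate 1 of exposed 48 h, the effect changed from 48 h to 72 h for 457 genes and in the joint test for 2343. Leaving out single libraries gave 1591 to 4945 genes from 48 h to 72 h and 2622 to 6428 in the joint test, with the highest without replicate 1 of exposed 48 h and without replicate 3 of non-exposed 60 h. Limma voom with sample quality weights called 9081 genes in the joint test and 7431 from 48 h to 72 h, with 3628 increases and 3803 decreases.

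The comparison of 72 h with 48 h in non-exposed mycelium gave the background of culture age. In exposed mycelium the same comparison cannot separate culture age from time under exposure. In exposed mycelium 4495 genes differed between 72 h and 48 h, with 1941 higher and 2554 lower at 72 h. Leaving out single libraries gave 2235 to 6716 genes, the fit of only the 6 libraries compared gave 2751, and sample quality weights gave 8406. With only replicate 1 of exposed 48 h, 116 genes were called, against 4033 with only replicate 2 and 5190 with only replicate 3. In non-exposed mycelium edgeR called 0 genes, with 1656 at an unadjusted p under 0.05. DESeq2 called 265 of the same genes tested, edgeR with only the 6 libraries compared called 1044, and limma voom with sample quality weights called 3360 (1848 higher and 1512 lower). Of the 100 most abundant genes, 54 were higher and 7 lower at 72 h in exposed mycelium, and 0 were called in non-exposed mycelium.

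Counts were concentrated in fewer genes in exposed libraries. The effective number of genes, the exponential of the Shannon entropy of the counts, was 2625 ± 274 in exposed and 3288 ± 314 in non-exposed libraries (SD, n = 9 each; exact permutation within times, p = 0.0005, adjusted p = 0.0025 over 5 measures). All exposed libraries lay below all non-exposed ones at 60 h and at 72 h, but not at 48 h, where the exact p was 0.2. The 100 most abundant genes held 36.1% ± 1.3 of counts in exposed and 27.2% ± 3.4 in non-exposed mycelium at 72 h, and 32.8% ± 2.6 against 23.3% ± 1.4 at 60 h (SD, n = 3 each). At 48 h they held 25.1% ± 4.1 against 27.8% ± 2.5, a difference within the spread between replicates. Over the 3 times this share differed with an exact permutation p of 0.0205 (adjusted p = 0.0256). Exposed libraries also had fewer genes with at least 1 count, 15433 ± 198 against 15629 ± 121 (exact permutation p = 0.00775, adjusted p = 0.0194). Their totals were larger, 35790214 counts on average against 34188947 (exact permutation p = 0.0385, adjusted p = 0.0385), but at 72 h they were smaller, 34715540 against 35807915.

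**Figure D4:**
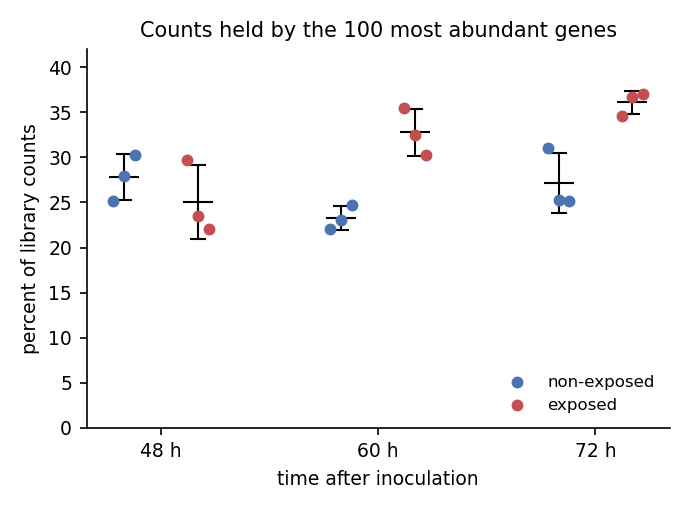
Percent of each library's counts held by the 100 genes with the highest mean CPM over the 18 libraries, by time; points are libraries, and bars are the group mean and SD (n = 3). At 60 h and 72 h the exposed libraries lie above all non-exposed libraries of that time, and at 48 h the groups overlap.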

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

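The results below were singled out because an exposure effect differed between time points by a test of the difference itself. Tests of a wrong time label, of depth, of a swap and of partial exposure were chosen after the library structure had been seen.

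The joint test gave 4188 genes whose exposure effect differed between the 3 times. Of 100 relabellings of exposure within times, 3 gave as many genes, the real one included, and the highest of the others gave 5052. The change from 48 h to 72 h took in 2832 genes. Again 3 of 100 relabellings gave as many, with 3235 the highest of the others. In the joint test both of the others kept 48 h and 72 h whole, with every label swapped at either 48 h or 72 h, and mixed the labels at 60 h. From 48 h to 72 h both kept the labels at 48 h and mixed them at 72 h, so the effect at 48 h remained in them. Relabelling within times removes the exposure effect itself, and relabellings with mixed labels at every time gave next to no genes. These shares therefore do not test whether the effect was the same at every time. For g14859 the adjusted p of the joint test was 0.00314, and for g11212 it was 0.0238, but neither passed the test from 48 h to 72 h (adjusted p = 0.11 and 0.188). g16808 and g11821 did not pass the joint test (adjusted p = 0.607 and 0.307).

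The exposed 48 h group was uneven, and with only its replicate 1 the effect changed from 48 h to 72 h for 457 genes, against 3136 with only replicate 2 and 4139 with only replicate 3. Replicate 1 lay at a root mean square log2 distance of 1.42 from the mean of replicates 2 and 3 but at 0.763 from the exposed 60 h mean. A lower depth of replicates 2 and 3 is argued against by their totals, the smaller of which was 93.8% of that of replicate 1. A weaker form of the response of replicates 2 and 3 is argued against for this library, in the correlations only by a small margin. The difference of replicate 1 from a control correlated with theirs at a mean r of 0.578 and with the 72 h effect, taken from 2 exposed and 2 non-exposed libraries, at 0.610. The explanation had predicted a better correlation with replicates 2 and 3. The mean difference was -0.0321, and below 0 with each control replicate (-0.014, -0.0265 and -0.0558). It was below 0 in only 24 of 27 overlapping choices of libraries, and asking for all 27 is stricter than the prediction was. A weaker form would also place replicate 1 between the 48 h controls and replicates 2 and 3. It lay between them on the first principal component (47.54, against 134.4 and 126.2). On the second it lay at 9.97, with the controls at -39.72 to -25.16 and replicates 2 and 3 at -91.3 and -98.35. The components were read in this way after the data were seen. An exchange of time labels between replicate 1 and an exposed 60 h library is argued against. Those libraries correlated at 0.964, 0.974 and 0.971 with their own group, and at 0.915, 0.926 and 0.926 with the exposed 48 h group. A wrong time label without such an exchange may account for the place of replicate 1. It cannot be told apart from a culture that had passed further through its response. The distance of replicate 1 to the exposed 60 h mean was 1.01 times the largest distance of an exposed 60 h library to the mean of the other 2. A mean of only 2 libraries is noisier, which makes this ratio lenient.

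The non-exposed 60 h libraries also split. Replicate 3 lay 1.38 from the mean of replicates 1 and 2, and the 3 libraries lay 1.23, 1.25 and 1.01 from the mean of the 48 h and 72 h controls. A swap with an exposed 60 h library is argued against, because each of those lay farther from the non-exposed mean than from its own group, by a ratio of at least 1.48. Partial exposure of replicates 1 and 2 stays open as a candidate explanation, as their difference from 48 h controls correlated across genes with the 72 h exposure effect, which shares no library with it, at r = 0.427, against 0.0202 for replicate 3. Culture stage at 60 h, which the design names, was not tested separately. Replicate 3 of the same time lacks the correlation but cannot serve as a reference for stage, since it stood apart itself (quality weight 0.1). In non-exposed 60 h replicates 1 and 2 the 100 most abundant genes held 22.05% and 23.06% of counts. All 48 h and 72 h controls held more (25.19% to 31.06%), whereas exposure at 72 h raised this share to 36.1%. At 48 h exposure did not raise it (25.1% against 27.8%).

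Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real split gave 6450, 2921 and 3652 genes at 48, 60 and 72 h and 4495 for time with exposure, as many as in 1 of 10 splits each, and the highest of the others gave 0, 3, 0 and 1. For time without exposure all 10 of 10 splits gave as many as the real 0, with 1 the highest. No split can give fewer than 0, so that share was fixed in advance and decides nothing. For the 780 genes shared by all 3 times, 1 of 100 relabellings, the real one, gave as many and the highest of the others gave 0. That comparison decides nothing, because other splits at a time call next to no genes and leave none to share.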

How the results depend on the processing

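Choices called added were made after seeing the data. The exposure counts at 48, 60 and 72 h stayed within 1.5 times with DESeq2 size factors, library totals only, no filter, the DESeq2 test, all FPKM fits, the length trend removed and thinning. The 4 named genes kept direction and significance in every setting run, but with only replicate 1 of exposed 48 h the log2 fold change of g16808 was 4.98 (adjusted p = 0.0284, over all settings 9.76e-11 to 0.0284) in place of 12.97, and on the log2(FPKM + 1) scale all 4 were smaller, at 3.68, 6.22, -4.47 and -3.81.

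Sample numbers gave no clear pairing of the libraries, and pairing was not tested. Deviations from group means correlated at a mean of 0.0172 over 45 pairs with the same number, 9 of them above 0.1. Over 90 pairs with different numbers the mean was -0.00816, with 10 above 0.1. Of the 18 libraries, 8 correlated best with a library of their own number. With the replicate number as a block the counts were 6409, 2850 and 3701 at 48, 60 and 72 h, 4140 in the joint test, 2995 from 48 h to 72 h, 0 and 4562 for time without and with exposure, and 752 shared by all 3 times.

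With only the compared groups in the fit, 5212 genes were called at 48 h, 529 at 60 h and 6578 at 72 h. For time, 1044 were called in non-exposed and 2751 in exposed mycelium. Added quality weights, which gave replicate 1 of exposed 48 h a weight of 0.146 and replicate 3 of non-exposed 60 h 0.1, called 4434 at 60 h, 7695 at 72 h, 9081 in the joint test, 7431 from 48 h to 72 h, and 3360 and 8406 for time without and with exposure. For time without exposure, the DESeq2 test called 265 genes and limma on log2(FPKM + 1) 35, or 69 without a filter, and edgeR 0. With only replicate 1 of exposed 48 h, an added setting, calls were 2856 at 48 h, 2343 in the joint test, 457 from 48 h to 72 h and 116 for time with exposure; that lone library is assumed to vary like the other groups. With the 48 h and 72 h controls used at 60 h, also added, calls were 4441 at 60 h and 2108 at all 3 times. The cause was not tested.

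Leaving out each replicate in turn gave 4879 to 7549 genes at 48 h, 1348 to 4150 at 60 h, 2298 to 2669 at 72 h, 2622 to 6428 in the joint test, 1591 to 4945 from 48 h to 72 h, 0 to 0 for time without exposure and 2235 to 6716 with it. Moves over 1.5 times came at 60 h from replicates 2 and 3 of exposed 60 h (1348 and 1909 without them), and at 72 h from replicate 2 of exposed 72 h (2298). In the joint test the libraries were replicate 1 of non-exposed 48 h (2622), replicate 3 of non-exposed 60 h (6428) and replicate 1 of exposed 48 h (6415). From 48 h to 72 h they were, in the exposed groups, replicates 1 and 3 of 48 h (4945 and 1664) and 1 and 2 of 72 h (1718 and 1810), and in the non-exposed groups replicate 1 of 48 h (1641) and 2 and 3 of 72 h (1630 and 1591). For time with exposure they were replicates 2 and 3 of exposed 48 h (2864 and 2235) and 1 and 2 of exposed 72 h (2901 and 2945).

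Library totals shifted the median log2 fold change to -0.30, -0.23 and -0.18 at 48, 60 and 72 h, and the share of rises from 55.3%, 46.6% and 52.9% to 34%, 30.7% and 33.8%. Limma on log2(FPKM + 1) gave 31%, 35.1% and 33.5%, and 54.3% for increases from 48 h to 72 h against 40.7%. Thinning every library to the smallest total gave 6423, 2924 and 3622 calls. The settings for gene lists were not run, as no list could be formed without names.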

Other observations

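The comparisons of 60 h controls and of abundant genes by library were chosen after seeing the data.

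Genes with neighbouring numbers moved together. At 72 h, log2 fold changes of genes 1 number apart correlated at a Spearman's rho of 0.213 over 13375 pairs, where the highest of 1000 shuffles of the numbers gave 0.0279, and at 50 numbers apart rho was -0.000808. Both members of 694 adjacent pairs were called the same way at 72 h, against a mean of 392.2 in shuffles, and 251 pairs were called opposite ways, against 389.6. Reads shared between adjacent genes alone are argued against, because genes 2 numbers apart also correlated (rho 0.101, highest shuffle 0.0282). Similar abundance or length of neighbours is argued against too, because rho was 0.212 after removal of both trends (highest shuffle 0.0301). If the numbers follow position in the genome, which the files do not state, clusters of co-regulated or duplicated genes may underlie the pattern; reads shared among near-identical tandem copies stay open, as no sequences were used here.

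The mean of the non-exposed 60 h libraries, which split as described above, differed from the other controls. Replicate 3 correlated at 0.930 and 0.936 with the 48 h and 72 h controls and at 0.883 with its own group. Against the mean of the 48 h and 72 h controls, edgeR called 2588 genes, with 1657 higher and 931 lower at 60 h. Of the 100 most abundant genes 1 was higher and 11 were lower. With the 48 h and 72 h controls in place of the 60 h ones, 53 of these 100 genes rose at 60 h and 1 fell. g14859, at 0 in all 48 h controls and at 0 to 2 counts in the 72 h controls, had 46 to 139 counts in the 60 h controls.

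At 48 h the most abundant genes differed with the libraries used. With only replicate 1 of exposed 48 h, 10 of the 100 rose and 2 fell, with a median log2 fold change of 0.40. Without replicate 1, 13 rose and 15 fell, with a median of 0.04.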
